A study of Mus musculus with 3 samples.

How the data were processed

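RNA from the nuclear fraction of mouse C57BL/6J macrophages grown from bone marrow was measured by total RNA-seq after ribosomal RNA depletion, per the labels. The cells had been treated with lipid A, the part of bacterial lipopolysaccharide that TLR4 recognises, at 100 ng/ml for 12 h, kept without it for 12 h, and given 100 ng/ml again for 15 min. The 3 libraries form 1 group and the labels number them as biological replicates 1 to 3. All 3 carry 1 donor identifier, and whether the cultures came from separate mice is not given in the sources used here, so p-values measure only spread between these samples. The labels give an RNA input of 1 µg for replicates 1 and 3 and 500 ng for replicate 2.

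The authors' gene and transcript tables were made from transcriptome alignments to mm10 with GENCODE M21, per the file headers and accompanying notes. Their columns are those that RSEM writes, and the tool and its version are not given in the sources used here. The expected counts are the authors' estimated, unnormalised counts per gene or transcript, deposited for each library separately. The deposited TPM values, and the posterior mean TPM beside them, were scaled by the authors to a fixed sum in each library. The deposited FPKM values are fragments per length and depth, as the authors' tool calculated them. A further transcript table with estimated counts and TPM was derived from the reads and an index, per the file headers, with the columns that kallisto writes. Its values were summed per gene. The 2 sets are called RSEM-format and kallisto-format values.

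The annotated genes numbered 55536, and all of their identifiers were found in GENCODE M21, which supplied symbols, classes and mm10 coordinates (counted from 1). Of the 141862 annotated transcripts, 141767 were in the kallisto-format table. For the 115 symbols with several identifiers, the identifier with the highest mean TPM was used. The 26248 rows with numeric identifiers, the 96 ERCC rows and the phiX row were left out of library sizes and tests. They held 0.827%, 0.275% and 0.0545% of the expected counts of replicates 1, 2 and 3 as phiX, 0 counts as ERCC in each library, and 10, 22 and 24 counts in the rows with numeric identifiers.

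TPM was analysed as log2(TPM + 1), and a gene was called detected at a TPM of at least 1 in all 3 libraries. List levels are medians over members, set against 10000 random lists of the same size from the detected protein-coding genes. Differences between lists were taken within each library and tested with an exact two-sided sign-flip test, whose smallest p with 3 libraries is 0.25. For counts, expected counts were rounded, genes were kept by filterByExpr and libraries were scaled by TMM. The edgeR 4.0.16 quasi-likelihood fit gave the common dispersion, each gene's quasi-dispersion over its trend, and the tests of each library against the others, with Benjamini-Hochberg adjustment and a threshold of 0.05. DESeq2 1.42.0 served as the alternative. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Both count tests were checked on simulated counts for 14350 genes with 50 genes changed at each fold. The changed genes had a mean count of at least 50. Every gene was drawn at the trended dispersion, without the scatter of real genes around that trend. The numbers recovered may therefore overstate what the tests find in these data. The test for excess variability recovered 8, 39, 48 and 44 of 50 genes at 2, 4, 8 and 16-fold, and the test of a library against the others recovered 7, 45, 50 and 43. Each made 4 calls among unchanged genes, and with no gene changed they made 1 and 0 calls.

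The gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each of 24 lists, the 4 members with the highest mean TPM and the detected member with the lowest. It added all NF-kappaB subunits, 10 set genes (Tnf, Il6, Il12b, Il10, Ifnb1, Nfkbia, Tnfaip3, Irak3, Nos2 and Tlr4), the 10 genes of any class and the 10 protein-coding genes with the highest mean TPM, and up to 10 protein-coding genes past the variability threshold. No gene came from that last part, since 0 genes passed. Some genes taken by the rule are not reported here. Genes named outside the rule are identified as such. The denominator of the shares was set to the sum over annotated genes after a first look at the values. The scaling over nuclear protein-coding genes was added after the data were seen. The alternatives covered the pseudocount, filters on low values, the unit, the scaling, the quantification, the tool and the omission of each replicate. No control or untreated library is analysed here, so no gene is described as induced or repressed.

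Short RNAs have a small effective length and take a large part of TPM, which lowers the TPM of all other genes alike within a library. Genes with near-identical copies, among them Rn7s1 and Rn7s2, the snRNA genes, the histone genes and the mitochondrial genes with nuclear copies, share reads, and their separate values are uncertain. Strand use in the quantification is not given in the sources used here, so values of antisense and overlapping genes are uncertain too. A count of 0 allows up to 3 counts, which is 0.126, 0.155 and 0.138 CPM in replicates 1, 2 and 3, for counting error only.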

Results

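Nuclear RNA of bone-marrow-derived macrophages was sequenced 15 min after a renewed lipid A stimulus that followed 12 h of pretreatment and 12 h of washout. The 3 libraries of this 1 group held 23826101, 19312032 and 21730342 expected counts over annotated genes in replicates 1, 2 and 3. A TPM of at least 1 in all 3 libraries was reached by 11261 genes, of which 9434 were protein-coding. The design holds no other group, so the values below describe levels in these nuclei and the spread between the cultures.

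Replicates ranked genes alike, and the highest levels belonged to short structural RNAs. Spearman correlations across 24320 genes, which are not independent replicates, were 0.934 for replicates 1 and 2, 0.938 for replicates 1 and 3, and 0.930 for replicates 2 and 3. The median SD of log2(TPM + 1) over 9863 protein-coding genes with a mean TPM of at least 1 was 0.20. Rn7sk, the 7SK RNA that holds the elongation factor P-TEFb inactive, had the highest mean TPM of all genes at 306158 ± 25003 (SD, n = 3). It lies on chromosome 9 from 78175303 to 78175633 in mm10. Rpph1, the RNA of RNase P, followed at 82872 ± 15947 TPM. Rn7s1 and Rn7s2, near-identical copies of the signal recognition particle RNA, each had 59251 ± 17089 TPM, and Rmrp, the RNA of RNase MRP, had 58892 ± 7932 TPM under the higher of its identifiers. The snRNA class gene Gm22513 had 11002 ± 3972 TPM.

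**Figure D1:**
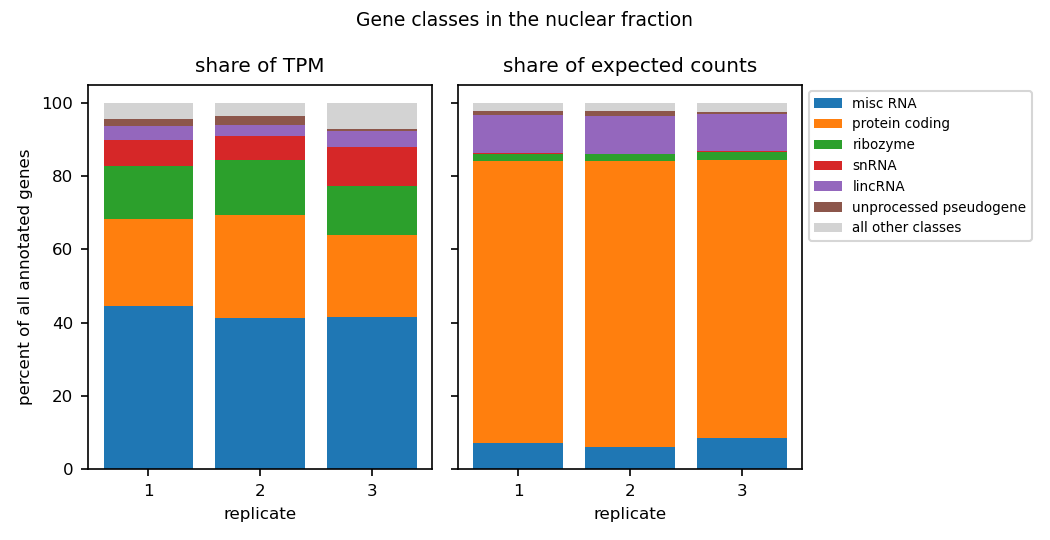
Percent of TPM (left) and of expected counts (right) held by gene classes in each of the 3 libraries, as stacked bars with 1 bar per replicate. Protein-coding genes hold 23.6%, 27.9% and 22.5% of TPM but 76.9%, 78.0% and 75.8% of expected counts in replicates 1, 2 and 3.

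Among protein-coding genes, Psap, which encodes the precursor of the saposins of the lysosome, had the highest mean TPM of those encoded in the nucleus at 3848 ± 679 (SD, n = 3). H2-K1, an MHC class I heavy chain, reached 2358 ± 194 TPM and Fth1, the ferritin heavy chain, 2191 ± 256 TPM. The mitochondrial genome supplied 7 of the 10 highest protein-coding genes, among them mt-Co1 with 10252 ± 3752 TPM and mt-Atp8 with 10354 ± 8964 TPM. Without replicate 2 the mean of mt-Atp8 was 5474 TPM, below the 8620 TPM of mt-Co1.

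Markers of macrophages were high, and markers of other blood and stromal cells were near 0. All 20 macrophage markers were detected. They were led by the lysosomal proteases Ctsd (1825 ± 141 TPM, SD, n = 3), Ctsb (1632 ± 204) and Ctss (1027 ± 25.2) and by the lysozyme gene Lyz2 (1616 ± 464). Of the markers of other cells, 0 of 11 for granulocytes, 0 of 8 for dendritic cells, 0 of 8 for fibroblasts and 0 of 6 for mast cells and basophils were detected. On TPM rescaled over nuclear protein-coding genes, some of these undetected markers had means over 1. Among them were Ccr7 (5.32 ± 2.04), S100a9 (3.94 ± 3.16), Ltf (2.80 ± 0.27) and Clec9a (1.51 ± 0.06). Replicate 1 carried the mean of S100a9, with 16, 4 and 4 expected counts in replicates 1, 2 and 3. The list of T and NK cells had 1 of 12 members detected, Cd4 with 19.9 ± 7.44 TPM, while Cd3g had 0.033 ± 0.058 TPM. For B cells 1 of 8 was detected, Cd22 with 6.32 ± 1.99 TPM. For erythroid cells 1 of 8 was detected, Alas2 with 2.21 ± 0.896 TPM. The macrophage list lay above the pooled other markers by 7.76 ± 0.18 (log2, SD, n = 3) and was higher in 3 of 3 libraries, with p = 0.25 in the exact two-sided sign-flip test, the smallest p that 3 libraries allow.

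**Figure D2:**
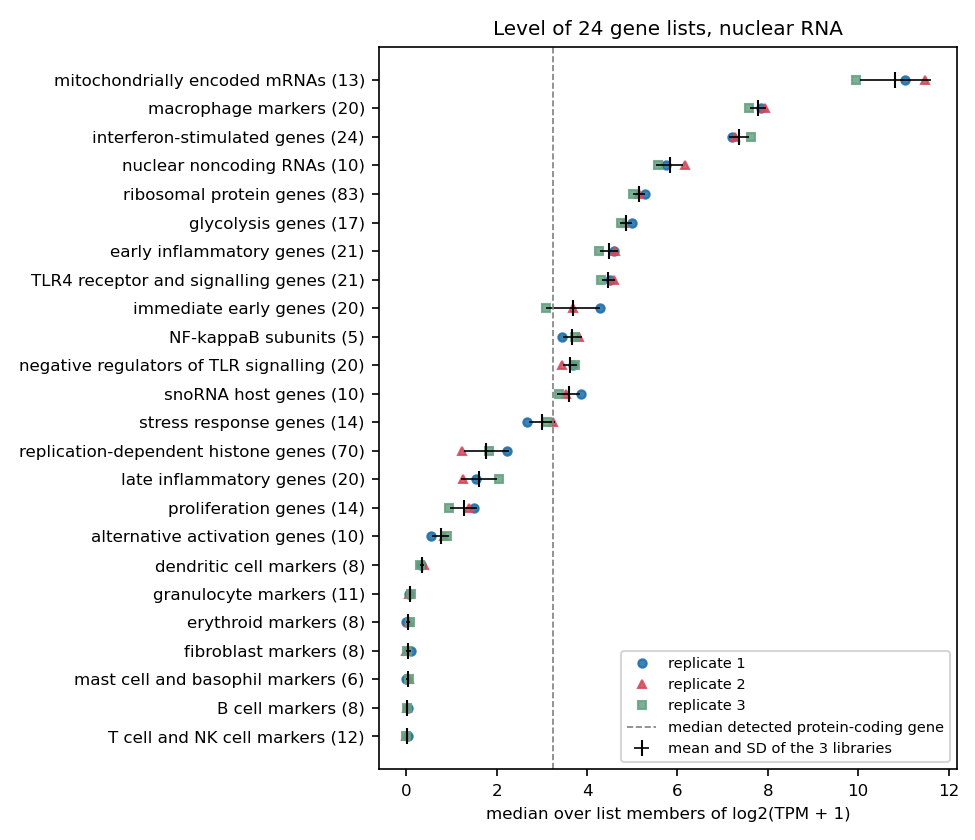
Median over list members of log2(TPM + 1) for 24 gene lists, with the number of members in brackets; symbols are the 3 libraries, the black mark is their mean with its SD, and the dashed line is the median detected protein-coding gene at 3.25. In all 3 libraries, 11 lists lie above that line.

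Interferon-stimulated genes stood far above the typical gene. The list had a median of 7.37 ± 0.23 (log2(TPM + 1), SD, n = 3), against 3.25 for the detected protein-coding genes, and exceeded all of the 10000 random lists. Rsad2, the antiviral protein viperin, had 855 ± 277 TPM and lies on chromosome 12 from 26442746 to 26456452. Ifit2 (656 ± 143 TPM), Mx1 (521 ± 173 TPM) and Ifit3 (388 ± 58.0 TPM), which encode antiviral proteins, came next. Of the 24 members 23 were detected, and the lowest detected was the exonuclease gene Isg20 at 23.1 ± 7.62 TPM. Ifnb1, which encodes interferon beta, had 2.03 ± 1.28 TPM, from 29, 15 and 63 expected counts in replicates 1, 2 and 3.

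Early inflammatory genes lay above the typical detected gene. The list median was 4.49 ± 0.20 (SD, n = 3), above 99.7% of the random lists, and 19 of 21 members were detected. Ccl4 (134 ± 29.4 TPM) and Ccl3 (115 ± 12.0 TPM), both chemokine genes, and Tnf (129 ± 37.3 TPM), the cytokine gene on chromosome 17 from 35199381 to 35202007, led the list, followed by the adhesion gene Icam1 (99.9 ± 20.0 TPM). Nfkbia, the NF-kappaB inhibitor, had 81.5 ± 22.7 TPM and Tnfaip3, the deubiquitinase A20, 40.9 ± 7.88 TPM. The lowest detected member was Tnfsf9 at 2.91 ± 0.581 TPM. Within a library the early list lay below the interferon-stimulated list by 2.61, 2.65 and 3.36 in replicates 1, 2 and 3 (mean difference -2.88 ± 0.42, exact sign-flip p = 0.25).

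Late inflammatory genes covered a wide range of levels. Saa3, an acute-phase protein gene on chromosome 7 from 46711998 to 46715700, reached 1396 ± 302 TPM (SD, n = 3), and the chemokine gene Ccl5 reached 811 ± 190 TPM. The scavenger receptor gene Marco had 346 TPM in replicate 1 but 46.1 and 69.1 TPM in replicates 2 and 3. Cp, the ceruloplasmin gene, had 50.6 ± 3.41 TPM. Il6, the interleukin-6 gene on chromosome 5 from 30013114 to 30019981, had 0.637 ± 0.015 TPM from 30, 27 and 32 expected counts. Il12b, a subunit of interleukin 12, had 3.22, 0.63 and 0.64 TPM, and Nos2, the inducible nitric oxide synthase, had 2.02, 2.48 and 7.27 TPM. Of the 20 members 10 were detected, with Ptges lowest at 3.85 ± 1.02 TPM, and the list median was 1.62 ± 0.40 (log2(TPM + 1)).

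The early list exceeded the late list by 2.87 ± 0.59 (log2, SD, n = 3) and was higher in 3 of 3 libraries, with an exact sign-flip p of 0.25. Restricting both lists to members with a mean TPM of at least 1 reduced the difference to 1.44 ± 0.25, and means in place of medians gave 1.62 ± 0.17.

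**Figure D3:**
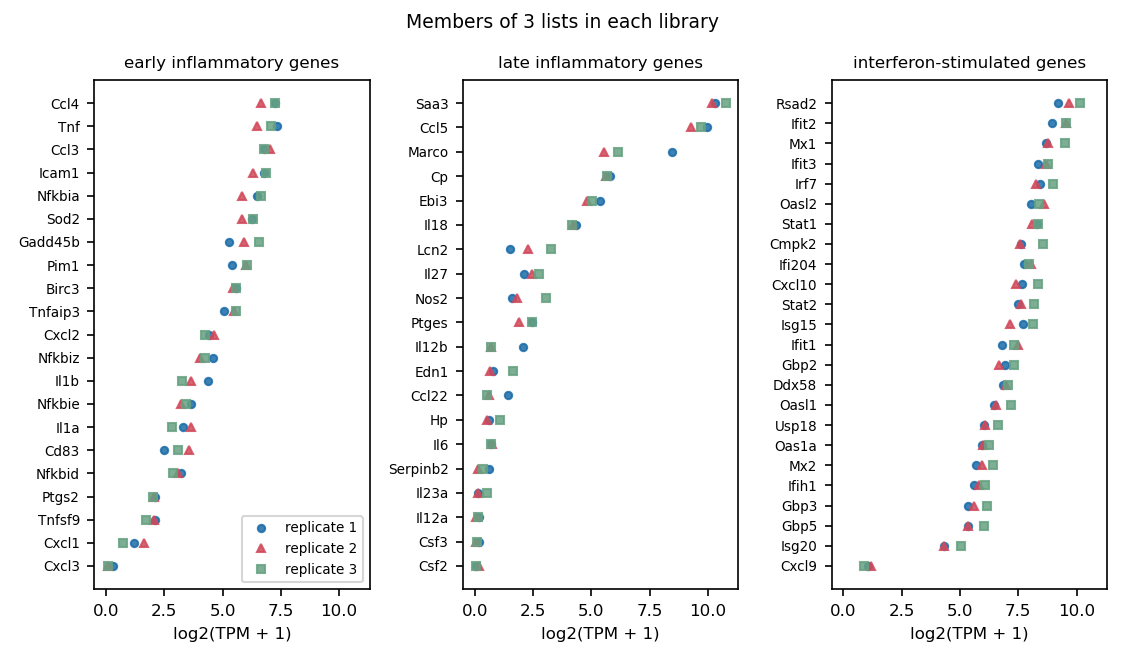
log2(TPM + 1) of each member of the early inflammatory, late inflammatory and interferon-stimulated lists, ordered by mean TPM, with 1 symbol per library. Saa3 and Ccl5 lie far above Il6 in the late list, and Marco in replicate 1 (346 TPM) lies above its values in replicates 2 and 3 (46.1 and 69.1 TPM).

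Immediate early genes were present in part. The list medians were 4.29, 3.70 and 3.10 in replicates 1, 2 and 3, and 14 of 20 members were detected. Zfp36, which encodes the mRNA-destabilising protein tristetraprolin, led with 116, 126 and 92.6 TPM in replicates 1, 2 and 3, followed by the transcription factor genes Junb (89.6 ± 20.5, SD, n = 3), Klf6 (80.9 ± 12.1) and Jun (39.0 ± 8.65). The lowest detected was Klf2 at 5.68 ± 1.52 TPM. Further members, chosen after their values were seen, were Egr1 with 20.3, 2.86 and 2.19 TPM Fos with 42.9, 32.8 and 7.79 TPM, and Atf3 with 25.2, 43.4 and 43.5 TPM in replicates 1, 2 and 3. The list lay below the early inflammatory list by 0.29, 0.93 and 1.16 (mean difference -0.79 ± 0.45, exact sign-flip p = 0.25). With members of a mean TPM of at least 1 the difference was -0.27 ± 0.26, higher in 1 of 3 libraries.

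Negative regulators of TLR signalling were detected in 19 of 20 cases. Acod1, which makes itaconate, had 203 ± 31.3 TPM (SD, n = 3), the phosphatase gene Inpp5d had 65.7 ± 5.17 TPM, and Tnip3, which encodes an A20-binding protein, had 57.4 ± 0.025 TPM. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, had 21.5, 36.9 and 32.9 TPM in replicates 1, 2 and 3. Irak3, the inhibitory kinase IRAK-M, on chromosome 10 from 120141648 to 120202130, had 13.1 ± 1.99 TPM, and Il10, the gene of the anti-inflammatory cytokine, had 10.1 ± 1.36 TPM. The lowest detected member was Dusp4 at 1.59 ± 0.246 TPM. The list exceeded the late inflammatory list by 2.00 ± 0.28 (log2) in 3 of 3 libraries (exact sign-flip p = 0.25). The size of this difference rested on the late genes with low values, since it was 0.26 ± 0.19 with members of a mean TPM of at least 1 and 0.86 ± 0.15 with means over members.

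All 21 genes of the TLR4 receptor and its signalling were detected, with a list median of 4.47 ± 0.14 (SD, n = 3). Ikbke, a kinase of the TBK1 family, had the highest level at 247 ± 33.5 TPM, and Cd14 (65.6 ± 21.8 TPM), which encodes a co-receptor for lipopolysaccharide, Tbk1 (44.9 ± 4.96 TPM) and Tab2 (31.3 ± 6.77 TPM) followed. Tlr4 had 24.3 ± 2.62 TPM and lies on chromosome 4 from 66827584 to 66930284. The adaptor gene Tirap was lowest at 2.90 ± 0.431 TPM. The 5 NF-kappaB subunits were all detected. Nfkb1 had 35.8 ± 2.27 TPM and Nfkb2 20.3 ± 3.95 TPM. Rel (10.7 ± 2.35), Relb (10.6 ± 1.56) and Rela (10.5 ± 0.947) differed by less than their spread between replicates in RSEM-format TPM. With kallisto-format TPM rescaled over nuclear protein-coding genes, Rel had 42.6 ± 6.10, Relb 51.8 ± 8.85 and Rela 65.0 ± 5.47.

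Glycolysis genes were all detected, 17 of 17, with a list median of 4.86 ± 0.12 (SD, n = 3). Hk3, a hexokinase gene, led with 191 ± 46.9 TPM ahead of Pkm (141 ± 14.8), Gapdh (84.2 ± 16.5) and Aldoa (55.8 ± 6.59), and the glucose transporter gene Slc2a1 was lowest at 3.07 ± 0.820 TPM. Of the alternative activation genes 4 of 10 were detected. The mannose receptor gene Mrc1 had a mean of 42.7 TPM (24.3 to 53.8 over the 3 libraries), Clec10a had 4.76 ± 1.96 TPM, Pparg had 3.40 ± 0.929 TPM and Chil3 had 1.93 ± 0.337 TPM. Stress response genes were led by the endoplasmic reticulum chaperone gene Hspa5 (175 ± 44.9 TPM), Atf4 (67.8 ± 7.97), Hmox1 (51.2 ± 20.7) and Ddit3 (46.4 ± 17.6), and 10 of 14 were detected. Proliferation genes were low, with 6 of 14 detected and a list median of 1.28 ± 0.30. Pcna, the sliding clamp of DNA replication, had 29.9 ± 6.86 TPM, while Top2a (4.69 ± 2.39), Mcm5 (4.63 ± 3.01) and Mcm2 (4.08 ± 2.24) were the next. Replicate 1 carried the mean of Mcm5, which was 8.09, 2.68 and 3.11 TPM in replicates 1, 2 and 3. Ribosomal protein genes had 77 of 83 members detected, led by Rpl41 (147 ± 21.7 TPM) and Rps24 (147 ± 52.8 TPM). Replication-dependent histone genes had 40 of 70 detected, led by Hist2h2aa2 (65.2 ± 24.1 TPM).

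RNAs known to stay in the nucleus were a large part of the RSEM-format TPM. The 10 nuclear noncoding RNAs took 39.9% ± 1.29 of TPM (SD, n = 3) and 15.5% ± 0.510 of expected counts, and Rn7sk supplied most of the TPM. Of the kallisto-format TPM they took 9.20%, 14.7% and 3.58% in replicates 1, 2 and 3. Malat1, the long RNA of nuclear speckles, had 13382 ± 4815 TPM, and Neat1, the scaffold of paraspeckles, had 659 ± 17.3 TPM. All 10 snoRNA host genes were detected, with Zfas1 (69.4 ± 13.9 TPM) and Gas5 (66.2 ± 15.6 TPM) highest and Snhg5 lowest at 5.74 ± 1.61 TPM.

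The share of mitochondrially encoded mRNAs differed between the libraries. The 13 mRNAs took 3.68%, 5.69% and 1.87% of TPM in replicates 1, 2 and 3, a mean of 3.75% ± 1.91 (SD, n = 3). Of expected counts they took 4.25%, 4.98% and 2.30%, and of kallisto-format TPM 1.30%, 2.87% and 0.239%. mt-Co1, a subunit of cytochrome c oxidase, had 11089, 13514 and 6152 TPM in replicates 1, 2 and 3, and mt-Atp8, whose gene is short, had 8459, 20113 and 2489 TPM. mt-Nd6 had 3663 ± 728 TPM and mt-Nd5 had 2455 ± 1091 TPM.

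Isoforms annotated as retaining an intron held 3.58% ± 0.349 of all transcript TPM (SD, n = 3) and 16.9% ± 0.745 of the transcript TPM of nuclear protein-coding genes, a denominator chosen after the data were seen. The share depended on the gene. In Tnip3 these isoforms held 76.9% ± 3.20 of the gene's TPM, in Cp 52.7% ± 5.54, in Ikbke 48.8% ± 1.53 and in Nfkb1 47.7% ± 1.79, whereas in Nfkbia they held 4.52% ± 1.14 and in Ctsd 1.07% ± 0.347. The median over 5980 detected protein-coding genes with such an isoform was 23.8%, 24.5% and 23.6% in replicates 1, 2 and 3. It was 45.4% ± 2.82 over 3 immediate early genes, 31.3% ± 2.95 over 13 interferon-stimulated genes, 27.2% ± 3.93 over 11 early inflammatory genes, 25.9% ± 2.66 over 16 TLR4 signalling genes, 19.5% ± 2.74 over 11 negative regulators and 18.1% ± 3.27 over 3 late inflammatory genes. It was 14.2% ± 0.877 over 62 ribosomal protein genes, 13.0% ± 0.740 over 14 glycolysis genes and 1.48% ± 0.712 over 4 macrophage markers. With kallisto-format values it was 28.4% ± 1.04 over the 5980 genes, 31.2% over the interferon-stimulated genes and 31.5% over the TLR4 signalling genes. It was 25.4% ± 5.66 over the early inflammatory genes and 3.33% over the macrophage markers. The early inflammatory list thus lay above the median of all genes with RSEM-format values and below it with kallisto-format values. In 766 of the 5980 genes the retained-intron isoforms held over 50% of the TPM. All these shares are of reads assigned to annotated transcripts. Reads of RNA not yet spliced in the nucleus cannot be told apart here from retained-intron isoforms. The share over all transcripts also depended on the unit, with 7.97% of expected counts against 3.58% of TPM.

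The kallisto-format values were compared by rank with the RSEM-format values of the same library. Spearman correlations across 93865 transcripts averaged 0.683 ± 0.016 (SD, n = 3 libraries) and across 34485 genes 0.718 ± 0.014. Among genes with a mean TPM of at least 1 the correlation was 0.925 ± 0.014. Of 131 named genes, 114 differed by over 2 times in mean TPM between the 2 sets of values, and 13 did after both were rescaled over nuclear protein-coding genes, a scaling chosen after the data were seen. Those 13 included mt-Co2, with a ratio of kallisto-format to RSEM-format values of 5.92, Gm22513 with 0.226 and mt-Atp8 with 0.333. The largest ratios, 12.8 for Sparc and 12.6 for Cd8a, rested on 2 to 9 expected counts per library.

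The spread between the cultures corresponded to a biological coefficient of variation of 0.213 over 14350 genes. Egr1, the early growth response factor, Dusp6, an ERK phosphatase, Etv5, an ETS transcription factor, and Marco were higher in replicate 1 than in replicates 2 and 3. All but Marco were named after their values were seen. In the edgeR quasi-likelihood test of replicate 1 against replicates 2 and 3, 30 genes were higher and 19 lower past the threshold. The log2 fold changes were 3.13 for Egr1, 2.61 for Dusp6, 2.43 for Etv5 and 2.63 for Marco. Such a test sets 1 library against 2 and cannot establish a difference between cultures. Each gene's own spread comes from those 2 libraries and is drawn strongly toward a trend over all genes. The count of 49 was 72 with DESeq2, 12 with edgeR on DESeq2 size factors and 0 with edgeR and no filter on low counts (891 at an unadjusted p under 0.05 as tested). Replicate 2, with the lower RNA input, gave 0 genes by edgeR (887 at an unadjusted p under 0.05) and 11 by DESeq2. Replicate 3 gave 1 gene by edgeR, Gm28438, a pseudogene, named after its value was seen, and 34 by DESeq2. No gene was more variable than the trend among the 14350 tested by edgeR, with 759 at an unadjusted p under 0.05, 0 with DESeq2 size factors, 502 with no filter on low counts and 27 without replicate 1. The smallest adjusted p was 0.0772, for Dmpk, the myotonic dystrophy kinase gene, named after its value was seen.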

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

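Reads assigned outside the annotated genes exceeded the 3 counts that a count of 0 allows in each library. The row of phiX, the phage whose DNA is added to sequencing runs as a control, held 198647 expected counts in replicate 1, 53233 in replicate 2 and 11859 in replicate 3. The rows with numeric identifiers together held 10 counts in replicate 1, 22 in replicate 2 and 24 in replicate 3. No biological or technical explanation was tested for either.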

How the results depend on the processing

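Rescaled TPM, nuclear protein-coding denominators, kallisto estimated counts and kallisto TPM for named genes were chosen after seeing the data. The means of the 5 list differences kept their direction under all alternatives, but none could pass the exact test. For early minus late genes, members with mean TPM of at least 1, means, log2 CPM and kallisto TPM gave 1.44, 1.62, 3.68 and 2.04. Early minus interferon-stimulated genes moved to -2.45 with members of mean TPM of at least 1. Immediate early minus early genes gave -0.27 with that filter (higher in 1 of 3 libraries, exact p = 0.5) and -1.27 with log2 CPM. Negative regulators minus late genes gave 2.46 with log2(TPM + 0.1), 0.26 with the filter, 0.86 with means, 3.02 with log2 CPM, 1.47 with kallisto TPM and 2.38 rescaled. Macrophage minus other markers gave 10.81, 5.55, 8.26 (FPKM), 8.71 (log2 CPM), 6.19 (kallisto TPM), 9.89 (rescaled) and 9.20 (kallisto rescaled), the first 2 with log2(TPM + 0.1) and the filter. Genes detected numbered 6353 at a TPM of at least 5, 6873 with kallisto TPM, 16416 at a TPM of at least 0.1, 14388 at an expected count of at least 10 and 15008 rescaled. Mean correlation between replicates was 0.965 with log2 CPM and 0.972 with Pearson, and a pseudocount of 0.1 cannot change ranks. The coefficient of variation was 0.237 with no filter and 0.203 to 0.221 leaving out 1 replicate. DESeq2 gave 0.132 as the square root of the median gene-wise dispersion, a different statistic from the common dispersion of edgeR. Genes more variable than the trend numbered 502 with no filter and 0 to 27 leaving out 1 replicate. Genes apart in replicate 1 numbered 12 with DESeq2 size factors, where the prior degrees of freedom fell from 13.6 to 9.74 and the median absolute log2 fold change was 1.78 against 1.77, and 0 with no filter. Replicate 2 gave 11 with DESeq2 and 349 with no filter, and replicate 3 gave 34 and 108. The mitochondrial share was 1.47% with kallisto TPM and 17.7% of nuclear protein-coding TPM. The nuclear noncoding share was 15.5% of expected counts, 44.9% without genes under 200 bases, 9.16% of kallisto TPM, 12.1% of kallisto estimated counts and 191% relative to nuclear protein-coding TPM. The retained-intron share was 1.75% of kallisto TPM, 7.97% of expected counts, 8.64% of kallisto estimated counts, 16.9% within nuclear protein-coding genes and 19.5% there with kallisto TPM. RSEM-format and kallisto-format values correlated at 0.801 over transcripts and 0.925 over genes with mean TPM of at least 1. For kallisto TPM, 3 miRNA-class genes held 59.7%, 28.4% and 84.4% of it in replicates 1, 2 and 3. This lowers the TPM of all other genes alike within a library, and with it the shares and the number of genes detected. The mitochondrial share was 3.53% of kallisto estimated counts against 3.84% of expected counts. Except for this and where the smaller denominator or gene set sets the change, the cause was not tested. Of 131 named genes, 107 moved by over 1 SD with kallisto TPM and 25 with posterior mean TPM, while leaving out 1 of 3 replicates cannot move a mean by 1 SD. Much of the first is a scaling common to all genes, since 114 genes over 2 times apart became 13 after rescaling. Genes with few counts, such as Il6, are limited by depth.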

Other observations

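Tests chosen only after the results they bear on were seen are the comparison of shares for the short miRNA-class genes, the check on RNA input, the fold check with length offsets and the check on short structural RNAs. The lists of ERK targets and of replication genes were written after the genes called for replicate 1 had been seen. Xist, the long RNA of the inactive X chromosome, had 72.8, 102 and 54.0 TPM in replicates 1, 2 and 3. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 0 counts in each library, where a count of 0 allows 0.126, 0.155 and 0.138 CPM. These genes were chosen after their values were seen, and the labels state no sex.

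The 49 genes called for replicate 1, in a test of 1 library whose count depends on the setting, included Mcm2, Mcm5, Mcm6, Uhrf1, Egr1, Dusp6 and Ccnd1. All but Mcm2 and Mcm5 were named after their values were seen, and no enrichment among the 49 was tested. A hypothesis is a stronger ERK response and more cells entering S phase in that culture. These genes prompted 2 lists of other members of the pathways, leaving out the called genes and those already seen, and both lists are given here. The 8 tested ERK targets had a median log2 fold change of 0.88, with 6 of 8 higher, and the 18 replication genes had 0.87, with 18 of 18 higher. Both medians lay above 100% of 10000 random lists matched on mean expression, but genes of a pathway are not independent. The hypothesis stays open, since it rests on 1 library. The planned immediate early and proliferation lists, read by gene after their values were seen, were also not uniform. Among the immediate early genes, Zfp36, Dusp1 and Maff had the highest TPM in replicate 2. Jun, Ier5, Atf3 and Klf6 were highest in replicate 3, and all other members in replicate 1. Most of the proliferation list had the highest TPM in replicate 1: Top2a, Cdk1, Pcna, Rrm2, Birc5, Aurkb, Bub1, Ccnb2 and the called genes Mcm2 and Mcm5. Mki67 (3.82 and 4.58 TPM in replicates 1 and 2), Ccna2 (1.13 and 2.24) and Ccnb1 (0.87 and 1.40) were highest in replicate 2. Plk1 had 0.25, 0.25 and 0.26 TPM in replicates 1, 2 and 3.

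The labels give replicates 1 and 3 the same RNA input, yet Egr1 had 20.3 and 2.19 TPM and Marco 346 and 69.1 TPM in them. This argues against RNA input for these 2 genes only, which were picked as higher in replicate 1. The order of replicates 1 and 2 by genes called turns round without the filter on low counts, so that order decides nothing about input. Replicate 2, with another input, had 0 genes called, though 11 with DESeq2 and 349 with no filter on low counts. Thinning every library to the smallest total, in 1 random draw, left 57 genes, which argues against depth. Offsets that removed each library's trend with gene length left 13 of the 49 genes called, while their median absolute log2 fold change stayed at 1.77, against 1.77 before, and the largest offset was 0.20. Offsets of that size could hardly move such folds, so the unchanged folds decide nothing by themselves. The small offsets argue against a trend shared by genes of similar length as the source of the folds. The number of calls stays open. The prior degrees of freedom fell from 13.6 to 9.58 alongside, and whether this ended the calls was not tested.

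The kallisto-format TPM was dominated by Gm24270, Gm23935 and Gm24245, 3 identical miRNA-class genes of 57 bases, chosen after their values were seen. They held 59.7%, 28.4% and 84.4% of TPM but 2.73%, 0.947% and 10.2% of estimated counts in replicates 1, 2 and 3. Their share of TPM was at least 8.29 times that of counts in each library. A high ratio follows from the short length itself, since TPM divides counts by effective length. It does not say why reads were assigned to these genes. Each had 283455, 99249 and 1052880 kallisto-format estimated counts in replicates 1, 2 and 3, but 0 RSEM-format expected counts in each library. Reads of the ribosomal repeat stay open, since 0% of their 27 distinct words of 31 bases occur in its annotated transcripts, which need not cover the repeat. By the rule written beforehand, words found in other transcripts spoke against the repeat, and 16 words were found in Gm24187. That gene, named because the words were found in it, is a further miRNA-class copy and decides nothing. The rule for words was therefore changed after this result to leave such copies out.

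The mitochondrial mRNA share differed between the highest and the lowest library by 3.05 times in TPM, a size that depends on the unit. Adding 7 nuclear pseudogene copies next to Gm28661 on chromosome 1, a gene named outside the rule, gave 5.36%, 8.11% and 2.54% in replicates 1, 2 and 3. The libraries stayed 3.19 times apart, which argues against reads shared with those copies as the source of the difference. Whether reads are shared at all was not tested, and if they are, the shares of the mRNAs alone may be too low. Relative to nuclear protein-coding TPM the mRNA share was 2.83 times apart between libraries, which argues against short structural RNAs as the cause. A differing carry-over of mitochondria stays open and was not tested. The mitochondrial rRNA genes took 0.0660%, 0.0211% and 0.293% of TPM in replicates 1, 2 and 3. The libraries were depleted of ribosomal RNA, so those shares cannot speak for or against carry-over. Among the mRNAs, mt-Nd4l (1651, 1300 and 1068 TPM), mt-Co3 (635, 513 and 466 TPM) and mt-Co2 (131, 88.1 and 118 TPM, with a posterior mean of 471 against a mean of 112) were highest in replicate 1. Of these, mt-Nd4l and mt-Co3 were named outside the rule, after their values were seen. All other mitochondrially encoded mRNAs were highest in replicate 2 and lowest in replicate 3.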
